A study of Mus musculus with 42 samples.

How the data were processed

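The deposited files held 3 kinds of measurement on thymocytes of C57BL/6 mice whose Kdm1a gene, which encodes the histone demethylase Lsd1, was either intact between loxP sites (WT) or deleted by a Cre recombinase driven from the CD2 promoter (KO). Bulk RNA-seq covered 16 libraries of sorted CD44-negative CD4+CD8+ double-positive (DP) cells low in TCR beta, 4 per genotype from the CD69-negative gate and 4 per genotype from the CD69-positive gate. ChIP-seq of whole thymus covered H3K4me1 and H3K4me2 (2 KO and 2 WT libraries each) and H3K4me3 (3 KO and 3 WT). Input libraries were listed in the labels and were not analysed here. Single-cell RNA-seq covered 2 WT and 2 KO samples of a sorted mixture of double-negative (DN), DP and CD8 immature single-positive cells.

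Bulk values were whole-number counts per gene that the authors deposited for each of 32 sequencing runs, 2 per library. Per the submitters' processing notes, reads were trimmed with cutadapt 2.4, aligned to mm10 with HISAT2 2.1.0 and counted with featureCounts 1.6.4; the strand setting is not given in the sources used here. The kit marked strand, per the labels' protocols, but without the setting the counts of overlapping genes are uncertain, as are those of near-identical copies (histone, haemoglobin, Oas, Ifit, Gimap, Slfn, Ly6 and TCR gamma constant genes). Single-cell values were whole-number UMI counts in unfiltered gene by barcode matrices that the authors deposited, made with bcl2fastq 2.20 and Cell Ranger 5.0.0 from 5' libraries per the submitters' processing notes. The peak lists that the authors deposited, 1 per library, gave for each peak a score, a fold enrichment ratio, and the −log10 of a p and of a q value. The deposited score equalled 10 times the −log10 p value, truncated to a whole number. Per the submitters' processing notes, cutadapt 2.1, Bowtie2 2.3.4.3, SICER 1.1, DiffBind 2.10.0 and deepTools 3.2.0 were named for the ChIP-seq; which input each list was called against is not given in the sources used here, and the lists carry no read depth. Peak scores and folds are the authors' own values and served only to rank, filter or describe peaks within a list.

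The 2 runs of a library were summed, because run-to-run differences (chi-square per degree of freedom 6.14 to 8.99) lay below those between libraries of a group (13.9 to 127). No column was left without a sample. Library totals ran from 18467377 to 23778462 counts over 54232 gene identifiers. Symbols came from a mouse gene table of assembly GRCm38.p6: 52480 identifiers matched with their version, 1599 without it, 77 through the single-cell feature table, 76 matched none, and 108 shared a symbol with another. The 19296 genes that edgeR's filterByExpr kept were tested in edgeR 4.0.16 (R 4.3.3) with TMM scaling and robust quasi-likelihood fits on all 16 libraries in a model of group means, so all groups shared 1 estimate of the spread (common dispersion 0.0355). The contrasts were KO against WT in each gate, CD69-positive against CD69-negative in each genotype, and the interaction, the KO step minus the WT step. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Levels are CPM, counts scaled to the normalised library total, and changes are log2 fold changes with their SE from edgeR.

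Before the data were examined, 22 gene lists, the cell type markers, the tests and the rule for named genes were fixed. The rule takes Kdm1a, Kdm1b, Gfi1, Bcl6 and Bcl11b always; per contrast the largest changes in each direction among called genes with a mean log2 CPM of at least 2 and no overlap between the libraries of the groups compared, leaving out gene models, pseudogenes and variable segments (10 and 8 for the CD69-negative contrast, 5 and 5 for the CD69-positive, 6 and 4 for the WT step, 4 and 4 for the KO step and for the interaction); per list up to 4 called members with the smallest p and the uncalled member with the highest CPM; per single-cell class 4 and 4 with a mean CPM of at least 20; and per mark the 3 KO-only and 2 WT-only regions with the highest mean score. Members named to complete a count of 5 or fewer were chosen after their values were seen. The lists were stem and progenitor, interferon-stimulated, Gfi1-repressed, Bcl6-repressed, Bcl11b-repressed, NK and cytotoxic, DP-stage, TCR signal, mature T cell and egress, cell cycle, p53 and apoptosis, Notch and pre-TCR, Lsd1 partners, H3K4 enzymes, germline, markers of B cells, macrophages, dendritic cells, epithelium and stroma, erythroid and gamma delta T cells, and dissociation stress. Each list was tested with limma 3.58.1 camera on voom values at a preset correlation of 0.01, adjusted over the lists of a contrast; camera with an estimated correlation and fry were run beside it. Members called were counted over all genes tested and again adjusted over the list alone. List median, mean and camera direction differed in sign in 13 of 110 bulk tests, 1 of them past the threshold, and in 15 of 104 single-cell tests, 0 of them past it.

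Barcodes with at least 10% of the UMIs of the 99th percentile of the largest barcodes were taken as cells (thresholds 2692, 2493, 3808 and 2659 UMIs in WT 1, WT 2, KO 1 and KO 2), with at least 500 genes and at most 10% mitochondrial UMIs. Doublets were scored with scrublet in scanpy 1.11.5. Its automatic threshold marked 58 of 15214 barcodes (0.381%), too few for the method to have worked, so a score of 0.25, chosen after seeing the data, was used and removed 284 (1.87%). Clusters were made from values of 2000 variable genes, centred per sample, without TCR and immunoglobulin segments, with 30 components, 20 neighbours and Leiden resolution 0.8, and were named by the fixed markers (at least 3 of them 1.5-fold above the other cells, and a margin of 0.5 over the next class, chosen after seeing the data). That margin left unnamed 1 cluster led by NK or innate-like markers (401, 269, 158 and 142 cells in WT 1, WT 2, KO 1 and KO 2) and 1 led by DN2/DN3 markers (273, 235, 118 and 64 cells). A further cluster, led by genes of dendritic cells and macrophages, stayed unnamed because genes of another type led it (15, 20, 28 and 21 cells). Raw UMIs were summed per sample and class, and classes with at least 50 cells in every sample were tested with edgeR, 2 WT against 2 KO samples. Cell type names are rebuilt here and may differ from the study's.

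Peaks of all libraries of a mark were merged; a KO-only region held a peak of every KO library and of no WT library, and the reverse for WT-only. Overlap meant at least 1 shared base. Coordinates are mm10/GRCm38, counted from 1. The gene table gave coordinates for 16166 of the 19296 tested genes (83.8%) and no strand, so either gene end with 1000 bp each side stood in for the planned promoter. A planned test of read counts per region was not run, since the lists hold no counts. Gene ends were compared by two-sided Fisher's exact tests, adjusted over 12 tests, and against 10000 gene sets matched in 20 bins of expression. Peak numbers and lengths were compared by exact two-sided permutation tests.

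Same-numbered libraries deviated together. In the groups compared directly, the correlation of their deviations from the group means was above 0.1 in every pair (lowest 0.228 for WT and KO in the CD69-negative gate, 0.118 in the CD69-positive gate, 0.108 between gates in WT and 0.227 in KO). Between CD69-negative WT and CD69-positive KO the lowest was 0.0327 and between CD69-negative KO and CD69-positive WT 0.0497. The replicate number was therefore taken to pair bulk libraries in the 4 direct comparisons and was a block in an alternative fit. The interaction was not taken as paired, although the between-gate pairs that its steps rest on passed 0.1. For single cells the labels tie each replicate to a shared sequencing run. Xist and Y-linked counts gave female, female, male, female for WT 1 to 4 and female, male, male, female for KO 1 to 4 in both gates; sex as a model term was an added alternative. Further alternatives were RLE scaling, DESeq2 1.42.0, other expression filters, only the groups compared in the fit, leaving out each replicate, and, added after seeing the data, leaving out mitochondrial genes and leaving out 2 libraries that stood apart (CD69-negative KO 2 with 43160 genes detected against 25430 to 35299 in the others, and CD69-positive WT 3 with 24.7% mitochondrial counts against 8.81% to 14.7%). For single cells, Leiden resolution, UMI minimum, mitochondrial limit, centring and doublet removal were varied; for peaks, only those above the median score of their list, 2 kb windows and genes changed at least 2-fold.

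Of the gene tests, the CD69-negative contrast and the DN2/DN3 class were tried on simulated data, and the other contrasts and classes were not. With 18895 simulated genes, 43.3% of those changed 1.5-fold, 77.6% of those changed 2-fold and 93.9% of those changed 3-fold were called in the CD69-negative contrast, and 0.048% of unchanged genes. For the DN2/DN3 class (9542 genes) the shares were 10.5%, 65.7% and 87.9%, and 0.032%. Intervals and floors (3 counts over a group) cover counting error only, at 95% confidence. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, anndata 0.12.19 and matplotlib 3.10.9 were used.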

Results

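Lsd1, the product of Kdm1a, removes methyl groups from lysine 4 of histone H3 and acts with repressors such as Gfi1, Bcl6 and Bcl11b. The series asked which gene programmes it holds down while T cells develop in the mouse thymus. WT and KO thymocytes were measured by bulk RNA-seq of sorted DP cells, in which CD69, an early marker of T cell receptor (TCR) signalling, split cells before and after the signal (4 libraries per genotype and gate, 16 in all). H3K4me1, H3K4me2 and H3K4me3 were profiled in whole thymus, and a mixture of sorted DN, DP and CD8 immature single-positive cells was profiled in single cells (2 samples per genotype). Bulk libraries held 18467377 to 23778462 counts. The labels call libraries of a group biological replicates without saying that each came from its own animal, so p-values measure the spread between these libraries. Bulk levels below are CPM, mean ± SD (n = 4), and changes are log2 fold changes ± SE with Benjamini-Hochberg adjusted p from edgeR's quasi-likelihood test.

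Kdm1a itself lay lower in every KO library than in every WT library of its gate. In CD69-negative WT libraries 1 to 4 it reached 126.8, 117.1, 117.4 and 131.4 CPM, and in the KO libraries 68.5, 62.2, 64.1 and 62.2 CPM. In the CD69-positive gate it reached 150.9, 137.1, 129.5 and 131.4 CPM in WT and 77.8, 79.7, 67.9 and 76.3 CPM in KO. The change was −0.94 ± 0.07 (adjusted p = 9.75e-09) and −0.86 ± 0.07 (adjusted p = 4.05e-08). Kdm1a lies on chromosome 4 (mm10, 136550533 to 136602787). Counts cover the whole gene, and the floxed deletion removes only part of it, so transcripts from the remaining part may still be counted. In single cells, Kdm1a fell in the DN2/DN3 class from 48.2 to 10.5 CPM (−2.15 ± 0.30, adjusted p = 0.00218), in the DP class from 52.4 to 9.88 CPM (−2.39 ± 0.41, adjusted p = 0.00235) and in the cycling class from 38.4 to 6.04 CPM (−2.66 ± 0.18, adjusted p = 2.30e-04). It stood at 21.1 ± 5.6 and 7.81 ± 0.31 CPM in WT and KO B cells (−1.37 ± 0.38, adjusted p = 0.686) and changed by −1.12 ± 0.37 in the NK or innate-like class (adjusted p = 0.223), neither past the threshold. The 5' tags of the single-cell libraries may also lie outside the deleted part.

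Loss of Lsd1 before the TCR signal was examined first, as KO against WT in CD69-negative DP cells. Genes nearly silent in WT were abundant in KO. Cd163l1, a scavenger receptor of gamma delta T cells, rose from 0.129 ± 0.0855 to 395 ± 26.9 CPM (11.53 ± 0.40, adjusted p = 1.74e-11; chromosome 7, 140197218 to 140231145), and Il18r1, a chain of the interleukin-18 receptor, from 0.446 ± 0.146 to 505 ± 66.0 CPM (10.11 ± 0.41; chromosome 1, 40465552 to 40500854). Olfr524, which lies inside the span of Cd163l1, changed by 11.26 ± 0.44, and its reads cannot be separated from those of its host with certainty. Chd7, a chromatin remodeller, rose from 1.32 ± 0.744 to 460.3 ± 14.1 CPM (8.46 ± 0.29). Blk, a Src-family kinase of B and gamma delta T cells, rose by 7.91 ± 0.30 and Atp8b4 by 7.84 ± 0.14 (adjusted p = 3.00e-17). The interferon-induced Oasl2 rose by 7.38 ± 0.40, the cathepsin gene Ctss by 7.30 ± 0.25, the transcription factor Maf by 7.16 ± 0.34 and Nucb2 by 6.50 ± 0.22. The largest falls were smaller. The secreted matricellular protein gene Smoc1 fell from 69.2 ± 15.1 to 5.44 ± 4.25 CPM (−3.68 ± 0.62, adjusted p = 5.07e-04) and the cystine transporter gene Slc7a11 from 163 ± 24.5 to 28.7 ± 3.39 CPM (−2.51 ± 0.43, adjusted p = 5.66e-04). Meis3, Ptk7, Prkcz, Cep85l, Tdrd5 and Adam12 changed by −2.46 to −2.04.

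**Figure D1:**
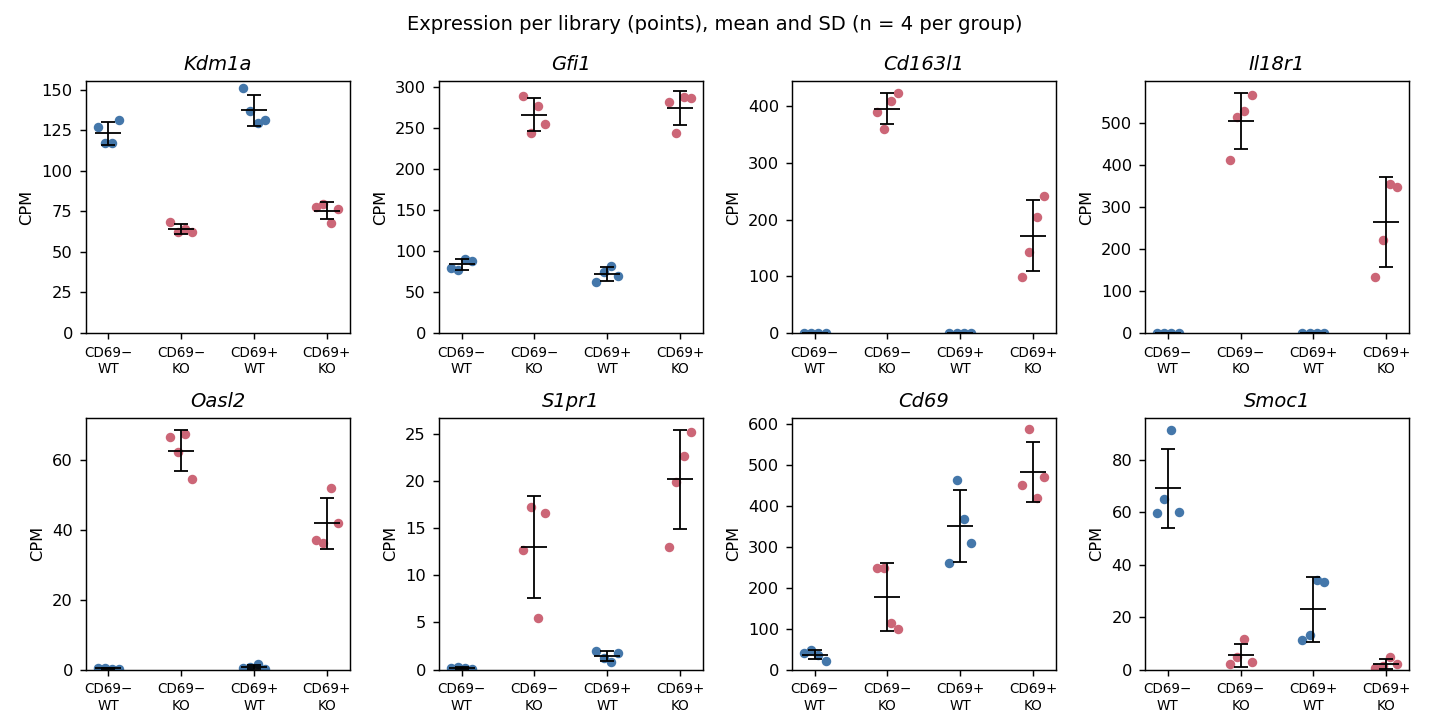
CPM, counts scaled to the library total (vertical axes), of Kdm1a, Gfi1, Cd163l1, Il18r1, Oasl2, S1pr1, Cd69 and Smoc1 in WT and KO libraries of the CD69-negative and CD69-positive gates, with points for single libraries and bars for the mean and SD (n = 4). Kdm1a lies at 117.1 to 150.9 CPM in WT and at 62.2 to 79.7 CPM in KO.

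Of 19296 genes tested, 3455 were higher and 3003 lower in KO. Of these, 2196 and 402 changed at least 2-fold. Among the partners of Lsd1, Gfi1, a repressor that recruits Lsd1, rose from 83.6 ± 6.54 to 266 ± 20.5 CPM (1.67 ± 0.09, adjusted p = 8.89e-11). Bcl6 fell from 194 ± 15.9 to 94.7 ± 13.9 CPM (−1.04 ± 0.12, adjusted p = 3.66e-06) and the related demethylase gene Kdm1b fell by 0.29 on the log2 scale (adjusted p = 0.0028). Bcl11b stood at −0.35 ± 0.18 (adjusted p = 0.147; past the threshold with the replicate number as a block, −0.36). Over the whole list of 20 partners, which includes Kdm1a itself, 5 rose, namely Gfi1, the corepressor genes Rcor3 (0.57) and Rcor1 (0.27), Mta3 (0.39) and Phf21a (0.20). The 8 that fell include the deleted Kdm1a (camera adjusted p = 0.218 for the list, 6 and 8 adjusted over the list alone). Chd4 stood at −0.01.

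Genes reported as repressed by these partners rose as groups. Of 22 genes reported as Bcl6 targets 19 were higher and 0 lower (camera adjusted p = 5.20e-10, 19 and 0 adjusted over the list alone). The T cell transcription factor Runx3 (2.67 ± 0.11) and the homing receptor Ccr7 (3.73 ± 0.18) rose. Cxcr3, at 3 or fewer counts in WT, was 121-fold higher in KO (counting interval 40.9 to 588). The cell cycle inhibitor Cdkn1b stood at 0.13. Of 18 reported Gfi1 targets 10 were higher and 0 lower (adjusted p = 1.54e-05, 11 and 0 adjusted over the list alone). The egress receptor S1pr1 rose from 0.184 ± 0.0687 to 13.0 ± 5.38 CPM (6.09 ± 0.46), the cytokine signalling inhibitor Socs3 by 1.75 and Foxo1 by 1.67. Rasgrp1 stood at −0.09. Of 19 reported Bcl11b targets 10 were higher and 1, Il4ra at −1.04, lower (adjusted p = 1.57e-04, 13 and 1 adjusted over the list alone, adjusted p = 0.0838 with an estimated correlation). The granzyme gene Gzma rose by 2.2 and Zbtb16, a factor of innate-like T cells, by 6.00, and Pdcd1 stood at 1.15 (adjusted p = 0.0748; called with the replicate block, 1.12). With an estimated correlation the Bcl6 and Gfi1 lists held (adjusted p = 0.0155 and 0.0225). These lists share members: S1pr1, Klf2, Il7r, Runx3 and others stand in more than 1.

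Interferon-stimulated genes moved almost as a block. Of 40 tested, 39 were higher and 0 lower (adjusted p = 5.44e-28, 39 and 0 adjusted over the list alone, adjusted p = 0.0531 with an estimated correlation). Gbp2 rose by 2.03 (11.2 ± 1.35 to 45.7 ± 4.42 CPM), Parp14 by 1.79 and the signal transducer Irf9 by 1.88. Stat2 stood at −0.10 (adjusted p = 0.456). Mature T cell and egress genes rose in 19 of 21 cases with 0 lower (adjusted p = 4.19e-17, 19 and 0 adjusted over the list alone, adjusted p = 0.00375 with an estimated correlation). Slfn1 rose by 7.10, the integrin gene Itgb7 by 3.77 ± 0.14 and the surface protein gene Ly6c1 by 7.87, while Gimap6 stood at −0.18. Stem and progenitor genes were higher in 6 of 13 cases and lower in 0 (adjusted p = 6.00e-04, 6 and 0 adjusted over the list alone, adjusted p = 0.0531 with an estimated correlation). Erg (5.49), Mef2c (3.69), the cytokine receptor gene Flt3 (4.55) and Hoxa7 (1.49) rose, and Irf8 stood at 0.34 (adjusted p = 0.259). NK and cytotoxic genes were higher in 6 of 13 (adjusted p = 0.00146, 7 and 0 adjusted over the list alone, adjusted p = 0.164 with an estimated correlation). Perforin (Prf1) rose by 2.38, Ctsw by 1.59 and Il2rb by 3.58, and Cd160 stood at 0.52 (called with the replicate block, 0.49). Notch and pre-TCR genes, active at the DN stage, were higher in 7 of 14 and lower in 1, the kinase gene Lck at −0.51 (adjusted p = 9.98e-04, 7 and 1 adjusted over the list alone, adjusted p = 0.0531 with an estimated correlation). Il2ra rose from 11 ± 2.62 to 97.5 ± 33.4 CPM (3.15 ± 0.22), Mpzl2 by 4.29, Il7r by 3.09 and Hes1 by 3.91. Cd3e stood at −0.00.

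TCR signal genes were higher in 15 of 26 cases and lower in 1, Cd6 at −0.24 (adjusted p = 4.53e-04, 17 and 2 adjusted over the list alone, adjusted p = 0.320 with an estimated correlation). Cd69 rose inside the CD69-negative gate, from 41.5, 48.0, 34.9 and 22.5 CPM in WT to 248.8, 249.3, 114.2 and 99.5 CPM in KO (2.28 ± 0.33, adjusted p = 1.38e-04). Irf4 rose by 2.45 and Ikzf2 by 1.46. Cell cycle genes fell in 14 of 28 cases and rose in 0 (adjusted p = 7.91e-11, 0 and 20 adjusted over the list alone, adjusted p = 0.166 with an estimated correlation). Cyclin E2 (Ccne2) changed by −1.44 ± 0.14 and the replication licensing genes Mcm2, Mcm5 and Mcm7 by −0.68, −0.93 and −0.61. The proliferation gene Mki67 stood at −1.0 (adjusted p = 0.154). Genes of the H3K4 enzymes fell in 8 of 16 cases and rose in 0 (adjusted p = 0.00242, 0 and 8 adjusted over the list alone, adjusted p = 0.164 with an estimated correlation). Kmt2c (−0.56 ± 0.08), Kmt2b (−0.36) and Setd1b (−0.49) were among them, and Kmt2d stood at 0.26 (called with the replicate block, also 0.26). DP-stage genes rose in 2 cases, Ccr9 (0.51) and Myb (0.30), and fell in 6 of 22, with 2 and 6 adjusted over the list alone. The list missed the threshold (adjusted p = 0.0514, with the replicate number as a block 0.0255, with an estimated correlation adjusted p = 0.572). It passed without CD69-negative WT 2 (0.0214), WT 3 (0.0414), KO 1 (0.0358), KO 3 (0.0295) or KO 4 (0.0168). Themis (−0.66 ± 0.16), Tcf3 (−0.64) and Ets2 (−0.96) fell, and the recombinase gene Rag1 stood at −0.31 (adjusted p = 0.685). Of 17 p53 and apoptosis genes 2 rose, Pmaip1 (2.93) and Bcl2l11 (1.24), and 2 fell, Gtse1 (−1.07) and Fas (−0.55) (adjusted p = 0.392). Trp53inp1 stood at 0.28 (called with the replicate block, also 0.28). The call of Bcl2l11 was lost when only the compared groups were fitted (1.30).

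Markers of other cells and signs of library quality moved beside these groups. Gamma delta T cell genes were higher in 8 of 10 cases (adjusted p = 6.69e-07, 8 adjusted over the list alone, adjusted p = 0.0531 with an estimated correlation) and dissociation stress genes in 10 of 15 (adjusted p = 9.21e-04, 11 adjusted over the list alone, adjusted p = 0.383 with an estimated correlation). Of 10 B cell markers 3 rose, Ebf1 (2.3), Cd74 (1.08, 2.27 ± 0.438 to 4.81 ± 2.3 CPM) and H2-Ab1 (1.09), and 1 fell, Ighm (−0.72). The list missed the threshold (adjusted p = 0.392) and Cd79b stood at −0.37. The calls of Cd74 (0.71) and H2-Ab1 (0.86) were lost without CD69-negative KO 1, and that of H2-Ab1 (1.00) without CD69-negative WT 4. Macrophage markers (4 tested, adjusted p = 0.206) held 1 that rose, Itgam (1.20), with Cd68 at 0.18. Dendritic cell markers (6, adjusted p = 0.0955) held Flt3 and Pld4 (3.33), with Cst3 at −0.06. The germline list (3, adjusted p = 0.106) held Sycp3 (3.65) and Tex15 (1.64), with Brdt at −0.22. Epithelial and stromal markers rose in 3 of 5 cases, Epcam (2.11), Cldn4 (2.73) and Pecam1 (0.84), with Col1a1 at 1.01 (adjusted p = 7.96e-04, 3 adjusted over the list alone, adjusted p = 0.0392 with an estimated correlation). Erythroid genes rose in 3 of 5, Hba-a2 (1.33), Hba-a1 (1.54) and Hbb-bs (1.36; adjusted p = 0.135 for the list), all under 10 CPM, and Alas2 stood at 0.07. Without CD69-negative KO 4 the dendritic and erythroid lists passed (adjusted p = 0.0499 for each). Without CD69-negative KO 3 the call of Hba-a1 was lost (1.09), and that of Hbb-bs was lost with the replicate block (1.27) and without any single library of the gate other than KO 4 (1.2 to 1.5). CD69-negative KO 2 held 43160 detected genes against 25430 to 35299 in the other libraries. Without it and CD69-positive WT 3, 3460 genes were higher and 2172 lower in KO.

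**Figure D2:**
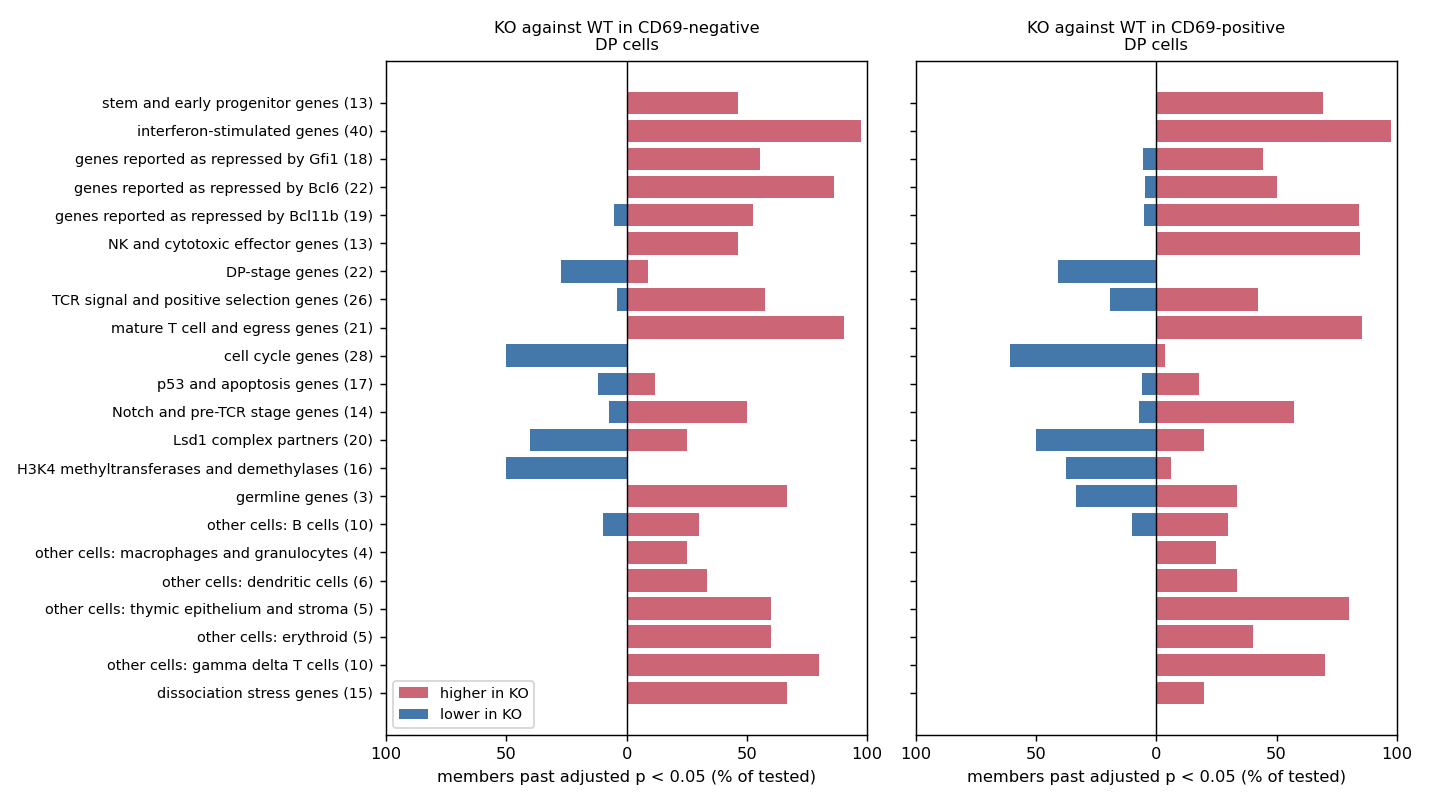
Share of the tested members of each of 22 gene lists that were higher (right) or lower (left) in KO, in percent, for the CD69-negative and the CD69-positive gate, at an adjusted p under 0.05 in edgeR. The interferon list has 39 of 40 members higher in either gate.

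After the TCR signal, KO against WT in CD69-positive DP cells gave 3751 genes higher and 3178 lower. Cd163l1 (9.78 ± 0.38), Olfr524 (9.94 ± 0.44), Il18r1 (8.18 ± 0.37), Ctss (7.34 ± 0.25) and Blk (6.73 ± 0.27) led the rises. Inpp4b, a phosphoinositide phosphatase gene, fell from 69.5 ± 10.6 to 7.78 ± 2.53 CPM (−3.16 ± 0.18), beside Smoc1 (−3.37 ± 0.65, adjusted p = 0.00128), Fn3k (−2.78 ± 0.38), Cfap74 (−2.76 ± 0.28) and Slc7a11 (−2.71 ± 0.46). Gfi1 rose by 1.93 ± 0.09 and Kdm1b, Bcl6 and Bcl11b fell (−0.55 ± 0.07, −0.64 ± 0.12 and −0.94 ± 0.18, the last with adjusted p = 7.65e-04). The interleukin-4 receptor gene Il4ra fell from 283 ± 41.9 to 69.0 ± 15.7 CPM (−2.03 ± 0.18). The costimulatory receptor gene Tnfrsf9 rose from 10.0 ± 4.56 to 192 ± 82.8 CPM (4.26 ± 0.43) and Myc from 23.2 ± 4.70 to 90.3 ± 29.5 CPM (1.96 ± 0.24).

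Here too, 39 of 40 interferon-stimulated genes were higher and 0 lower (adjusted p = 2.88e-24, 39 and 1 adjusted over the list alone, adjusted p = 0.0675 with an estimated correlation). Oas1a rose by 6.00, Parp14 by 1.69 and Gbp2 by 1.75, and Stat2 stood at −0.23 (adjusted p = 0.0571; called with the replicate block, also −0.23). Mature T cell genes were higher in 18 of 21 and lower in 0 (adjusted p = 2.19e-14, 19 and 0 adjusted over the list alone, adjusted p = 0.00789 with an estimated correlation). Slfn1 (5.51), Ly6c1 (7.26), Ccr7 (3.90) and Il7r (3.03) were among them. The stem list held 9 higher and 0 lower of 13 (adjusted p = 9.82e-06, 9 and 0 adjusted over the list alone). Mef2c rose by 5.28, Irf8 by 2.38 and the stem cell factor receptor Kit by 3.30, and Erg was 62.7-fold higher (counting interval 21.2 to 307). The Bcl11b list held 16 higher and 1 lower, Il4ra (adjusted p = 1.82e-06, 16 and 1 adjusted over the list alone). The Bcl6 list held 11 and 1, Gata3 at −0.36 (adjusted p = 4.88e-06, 12 and 1 adjusted over the list alone), and the Gfi1 list 8 and 1, Rasgrp1 at −0.39 (adjusted p = 1.32e-04, 8 and 1 adjusted over the list alone). NK genes were higher in 11 of 13 cases and lower in 0 (adjusted p = 9.82e-06, 11 and 0 adjusted over the list alone, adjusted p = 0.0675 with an estimated correlation), Prf1 at 1.85, Ctsw at 2.04 and Il2rb at 3.59 ± 0.35. With an estimated correlation, adjusted p was 0.0282 for the stem, 0.0368 for the Gfi1 and Bcl6, and 0.0382 for the Bcl11b list.

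DP-stage genes fell in 9 of 22 cases and rose in 0 (adjusted p = 1.97e-04, 0 and 10 adjusted over the list alone, adjusted p = 0.333 with an estimated correlation). Themis, needed for positive selection, fell from 700.3 ± 122.5 to 281.8 ± 72.3 CPM (−1.31 ± 0.16), Lef1 by −0.79 and Satb1 by −0.75. Cell cycle genes fell in 17 of 28 cases and rose in 1, Ccne1 at 0.82 (adjusted p = 0.00385, 1 and 18 adjusted over the list alone, adjusted p = 0.542 with an estimated correlation), Plk1 at −1.42, Kif11 at −1.64 and E2f1 at −0.95. One WT library of this gate, WT 3, carried 516.5 CPM of the proliferation gene Mki67 against 70.5, 94.6 and 121.6 CPM in the other WT libraries, and 24.7% mitochondrial counts. TCR signal genes were higher in 11 of 26, Bcl2a1d at 2.53 among them, and lower in 5, namely Bcl2 (−0.78), Tox (−0.82), Cd6 (−0.44), Rasgrp1 and Gata3 (adjusted p = 0.0312, 11 and 5 adjusted over the list alone, adjusted p = 0.542 with an estimated correlation). That list's call was lost without CD69-positive WT 3 (adjusted p = 0.0741), WT 4 (0.0905) or KO 1 (0.0555), and without the pair of libraries that stood apart (0.0535). Notch genes were higher in 8 and lower in 1, Lck at −0.62 (adjusted p = 0.00877, 8 and 1 adjusted over the list alone, adjusted p = 0.109 with an estimated correlation), Il2ra by 4.31. H3K4 enzyme genes were higher in 1, Wdr5 at 0.25, and lower in 6 (adjusted p = 0.0174, 1 and 6 adjusted over the list alone, adjusted p = 0.243 with an estimated correlation), Kmt2c by −0.79 and Kdm5a by −0.36. Epithelial markers were higher in 4 of 5, Epcam (2.47), Cldn4 (2.68), Pecam1 (0.92) and Col1a1 (1.20) (adjusted p = 0.00104, 4 adjusted over the list alone, adjusted p = 0.0368 with an estimated correlation). The call of Col1a1 was lost without any single library of the gate (1.09 to 1.27). Gamma delta genes were higher in 7 of 10 (adjusted p = 2.46e-05, 7 adjusted over the list alone, adjusted p = 0.0985 with an estimated correlation). Partner, p53, germline, B cell, macrophage, dendritic and erythroid lists missed the threshold (adjusted p = 0.144, 0.337, 0.493, 0.272, 0.107, 0.0776 and 0.12), the last passing without CD69-positive KO 4 (0.0484).

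The step from CD69-negative to CD69-positive cells in WT gave the background for the same step in KO. TCR signal genes rose in 24 of 26 cases and fell in 0 (adjusted p = 8.78e-18, 25 and 0 adjusted over the list alone, adjusted p = 0.221 with an estimated correlation). Tox rose by 2.51 ± 0.12, the survival gene Bcl2 by 2.88 ± 0.14, the costimulatory receptor Cd28 by 1.70, Cd6 by 1.61 and Cd69 by 3.26 ± 0.35. The largest rises were in the adhesion gene Chl1 (0.521 ± 0.454 to 46.8 ± 14.8 CPM; 6.50 ± 0.52), the inhibitory receptor Btla (6.01 ± 0.29), Nr4a3 (5.62 ± 0.76), Zbtb10 (4.55 ± 0.60), Ephx1 (4.45 ± 0.29) and Itm2a (8.89 ± 1.33 to 186 ± 70.8 CPM; 4.39 ± 0.29). The pre-TCR alpha chain gene Ptcra fell from 15.9 ± 2.36 to 1.06 ± 1.00 CPM (−3.92 ± 0.55), and the histone genes Hist1h2af, Hist1h3c and Hist1h3g by −3.80 ± 0.38, −3.72 ± 0.45 and −3.68 ± 0.41. All 28 cell cycle genes fell (adjusted p = 5.56e-23, 28 adjusted over the list alone, adjusted p = 0.243 with an estimated correlation), Mcm3 by −1.66 and Rrm1 by −1.89. Of 22 DP-stage genes 2 rose, Lef1 (2.15 ± 0.12) and Ikzf1 (1.02), and 14 fell, Cd4 by −1.61 and Bcl2l1 by −1.36 (adjusted p = 0.00146, 4 and 14 adjusted over the list alone, adjusted p = 0.763 with an estimated correlation). Mature T cell genes rose in 13 cases and fell in 1 (adjusted p = 0.00195, 13 and 1 adjusted over the list alone, adjusted p = 0.372 with an estimated correlation). Bcl6 targets rose in 11 cases, Gata3 by 1.51 and Runx2 by 2.17, and fell in 2, Selplg (−1.08) among them (adjusted p = 0.0110, 12 and 2 adjusted over the list alone, adjusted p = 0.459 with an estimated correlation). In all 3869 genes rose and 3943 fell. Kdm1a stood at 0.16 (adjusted p = 0.0868; called with the replicate block, 0.15) and Gfi1 at −0.22 (adjusted p = 0.0593; called with the block, −0.21).

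In KO the step raised 3690 genes and lowered 4138. TCR signal genes rose in 25 cases and fell in 0 (adjusted p = 5.68e-18, 25 and 0 adjusted over the list alone, adjusted p = 0.201 with an estimated correlation). Tnfrsf9 rose from 2.39 ± 0.927 to 192 ± 82.8 CPM (6.32 ± 0.49), and Tox (1.93 ± 0.12), Bcl2 (2.16 ± 0.14) and Ikzf2 (2.36) rose less. Ephx1 (4.49 ± 0.29), Arhgap20 (4.43 ± 0.24) and Lysmd2 (3.91 ± 0.32) also rose. Cell cycle genes fell in 26 of 28 cases (adjusted p = 5.31e-15, 26 adjusted over the list alone, adjusted p = 0.528 with an estimated correlation), Plk1 by −3.40 ± 0.30 and E2f1 by −2.29. With them fell E2f8 (−4.51 ± 0.65), Hist1h2af (−4.56 ± 0.45), Hist1h3b (−4.52 ± 0.67) and Hist1h3c (−4.40 ± 0.50). DP-stage genes rose in 3 cases, Lef1 (1.45), Ikzf1 (0.84) and Bcl6 (0.58), and fell in 16 (adjusted p = 5.38e-05, 3 and 16 adjusted over the list alone, adjusted p = 0.626 with an estimated correlation), the terminal transferase gene Dntt by −2.83 ± 0.33. Kdm1a stood at 0.23 (adjusted p = 0.0145), a call lost without the pair of libraries that stood apart (0.16) and with mitochondrial genes left out (0.18). The gamma delta list passed with the replicate number as a block (adjusted p = 0.0328 against 0.0508), as did the stress list (0.0355 against 0.112). The gamma delta list also passed without CD69-negative KO 1 (0.0469), KO 2 (0.0380) or KO 3 (0.0281), CD69-positive KO 1 (0.0360) or KO 4 (0.00328) or the pair of libraries that stood apart (0.0415). The stress list passed without CD69-negative KO 1 (0.0469) or KO 2 (0.00530), CD69-positive KO 4 (0.0404) or that pair (0.00249), and the interferon list without CD69-negative KO 4 (0.0313 against 0.179).

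Whether the step differed between genotypes was tested as the interaction, the KO step minus the WT step. It was positive past the threshold in 927 genes and negative in 688. The split turned when mitochondrial genes were left out (692 positive, 829 negative) and with a minimum mean of 1 CPM (764 and 935). AI506816 changed most on the positive side (3.20 ± 0.46, adjusted p = 8.52e-04). It went from 29.4 ± 10.1 in WT to 17.4 ± 3.84 CPM in KO in CD69-negative cells and from 16.1 ± 3.37 to 87.7 ± 37.5 CPM in CD69-positive cells. Next came Lap3 (2.56 ± 0.41), the polyamine synthesis gene Srm (2.52 ± 0.38) and Bcat1 (2.51 ± 0.39). On the negative side stood Tox2 (−3.65 ± 0.24, adjusted p = 1.94e-07), Btla (−3.45 ± 0.35), Chd7 (−3.44 ± 0.33) and Zbtb10 (−3.06 ± 0.75, adjusted p = 0.0239). Tox2 held 2.77 ± 0.501 CPM in CD69-negative WT and 45.8 ± 7.78 CPM in KO, against 32.0 ± 7.19 and 42.1 ± 5.58 CPM in CD69-positive cells. The call of Zbtb10 was lost without CD69-negative WT 2 (−2.98), WT 3 (−3.07) or WT 4 (−2.93).

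Among lists, mature T cell genes had a smaller step in KO (0 positive and 4 negative, adjusted p = 0.0014, 0 and 5 adjusted over the list alone), with Ms4a6b at −1.31, Itgb7 at −0.91, Slfn1 at −1.59 and S1pr1 at −2.31. Adjusted p was 0.645 with an estimated correlation. Bcl6 targets also passed (0 and 3, Gata3 at −0.92 ± 0.14, S1pr1 and Cd69 at −1.82, adjusted p = 0.0200, 0 and 3 adjusted over the list alone, adjusted p = 0.753 with an estimated correlation). So did TCR signal genes (1 and 5, adjusted p = 0.0200, 2 and 9 adjusted over the list alone, adjusted p = 0.927 with an estimated correlation), Myc at 1.62 ± 0.33 against Gata3, Cd69, Cd28 (−0.65), Bcl2 (−0.72) and Tox (−0.58). For cell cycle genes (5 and 0, adjusted p = 0.0320, 6 and 0 adjusted over the list alone, adjusted p = 0.927 with an estimated correlation), Rrm1 at 1.03, Mcm3 at 0.87, Mcm5 at 0.83, Ccne2 at 0.79 and Mcm7 at 0.59, the test was positive while the list's median and mean were negative. The TCR call was lost without CD69-negative KO 1 (adjusted p = 0.0823) or KO 2 (0.0670), CD69-positive WT 1 (0.0628) or KO 3 (0.0706). The cell cycle call was lost without CD69-negative WT 2 (0.0591) or KO 1 (0.0823) or CD69-positive WT 1 (0.198), WT 2 (0.248) or WT 4 (0.0913) and with sex as a term (0.0764). Without the pair of libraries that stood apart the TCR (0.0518) and Bcl6 calls (0.0755) were lost. The call of S1pr1 was lost (−2.52 to −2.06) without any library other than CD69-negative KO 3 and CD69-positive WT 3, KO 3 and KO 4. That of Cd69 was lost without CD69-negative WT 3 (−1.75), KO 1 (−1.57) or KO 2 (−1.61) or CD69-positive WT 2 (−1.61) or KO 1 (−1.78), and that of Bcl2 was lost without CD69-negative WT 3 (−0.68), WT 4 (−0.67) or KO 1 (−0.58) or CD69-positive WT 2 (−0.64). Interferon genes, with Zbp1 at −0.95, missed the threshold (adjusted p = 0.0879) and passed without CD69-negative WT 3 (0.0156), KO 2 (0.0247) or KO 4 (0.00731) or CD69-positive WT 4 (0.00401), KO 1 (0.0202) or KO 3 (0.0329). The DP-stage list (0.119) passed without CD69-negative KO 2 (0.0247), CD69-positive KO 4 (0.0189) or the pair that stood apart (0.0459), and the stem list (0.190) without that pair (0.0459).

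H3K4 methylation was compared through the authors' peak lists, called per library. H3K4me1 peaks numbered 35105 and 33373 in KO and 24802 and 21255 in WT (mean ± SD 34239 ± 1225 and 23028 ± 2508, ratio 1.49). The exact two-sided permutation p was 0.333, the smallest that 2 against 2 allows. Covered length was 135 ± 11.7 Mb in KO and 120.2 ± 59.4 Mb in WT (ratio 1.13, exact p = 1). Without H3K4me1 WT 2 the ratio was 0.835 and without WT 1 it was 1.73. H3K4me2 peaks numbered 19812 and 24844 in KO and 27122 and 28130 in WT (22328 ± 3558 and 27626 ± 713, ratio 0.808, exact p = 0.333). They covered 86.8 ± 9.84 and 83.1 ± 3.20 Mb (exact p = 1). H3K4me3 peaks numbered 12668, 14808 and 17755 in KO and 13619, 14060 and 13512 in WT (ratio 1.1, exact p = 0.6, with 0.1 the smallest possible). They covered 33.5 ± 4.61 and 25.3 ± 10.2 Mb (exact p = 0.3). None of these designs can reach p under 0.05 and the lists give no depth.

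Regions found in every KO library and no WT library numbered 3850 for H3K4me1, 293 for H3K4me2 and 430 for H3K4me3. The reverse kind numbered 475, 2555 and 8. Other splits of a mark's libraries gave at most 926 for H3K4me1 (above WT-only), 482 for H3K4me2 (above KO-only) and 495 for H3K4me3 (above both). For H3K4me1 and H3K4me2 counts grew when a library was left out and fewer had to match. Mean peak overlap was 61.5% within and 58.9% between genotypes for H3K4me1, 88.7% and 84.4% for H3K4me2 and 79.7% and 77.7% for H3K4me3. For H3K4me1, WT 2 overlapped 43.3% of WT 1 peaks, and KO 1 and KO 2 80.4% and 81.1%. The KO-only H3K4me1 regions with the highest scores lay at Cog7 (chromosome 7, 121927001 to 121941598, RNA change 0.80), Rab11fip2 (chromosome 19, 59923801 to 59933598, RNA 1.03) and inside Chd7 (chromosome 4, 8726201 to 8741998, the authors' fold enrichment 2.72 ± 0.47, n = 2), the remodeller gene whose RNA rose. Those of H3K4me2 lay at the end of Blk (chromosome 14, 63409401 to 63418598), at Zp1 (chromosome 19, 10914001 to 10922598, RNA change 6.57 ± 0.52) and at Tshz2 (chromosome 2, 170021001 to 170025798). Those of H3K4me3 included Oasl2 (chromosome 5, 114896401 to 114899798, fold enrichment 13.9 ± 4.59, n = 3) and a region 7148 bp from Cbx5 (chromosome 15, 103182001 to 103184398), a gene whose RNA fell by 0.84. WT-only regions stood at Zfp428 (RNA 0.08, adjusted p = 0.873) and Basp1 (RNA 1.43 ± 0.23, adjusted p = 1.80e-04) for H3K4me1, Gucy1b1 (RNA −0.68, adjusted p = 0.491) and Dnaja4 (RNA −0.31, adjusted p = 0.572) for H3K4me2, and Hoxb5os for H3K4me3.

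Genes higher in KO carried KO-only regions at their ends more often than genes without a call. For H3K4me3, 105 of 2995 genes higher in CD69-negative KO cells (3.51%) had one within 1 kb of an end, against 29 of 10401 genes without a call (0.279%, odds ratio 13.0, two-sided Fisher's exact test, adjusted p = 2.55e-42). Cd163l1, Il18r1, Blk and Oasl2 were among the former. For H3K4me2 it was 30 (1.00%), Blk among them, against 6 (0.0577%, odds ratio 17.5, adjusted p = 7.45e-14). For H3K4me1 it was 94 (3.14%) against 134 (1.29%, odds ratio 2.48, adjusted p = 6.99e-10), with Cd163l1, Il18r1 and Blk again. Sets of genes matched in expression held at most 18, 6 and 59. WT-only H3K4me1 regions stood at 96 of 2770 genes lower in KO (3.47%) against 244 of 10401 (2.35%, odds ratio 1.49, adjusted p = 0.00444). Of the 12 tests 8 missed the threshold, among them WT-only H3K4me2 regions at lower genes (40, odds ratio 0.672, adjusted p = 0.0512). Single libraries moved the ratios: it was 1.15 for H3K4me1 without WT 2, 6.34, 6.84 and 9.23 for H3K4me2 without KO 1, KO 2 or WT 2, and 6.02 and 4.00 for H3K4me3 without KO 1 or WT 3. With peaks above the median score of their list it was 2.48 for H3K4me3.

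**Figure D3:**
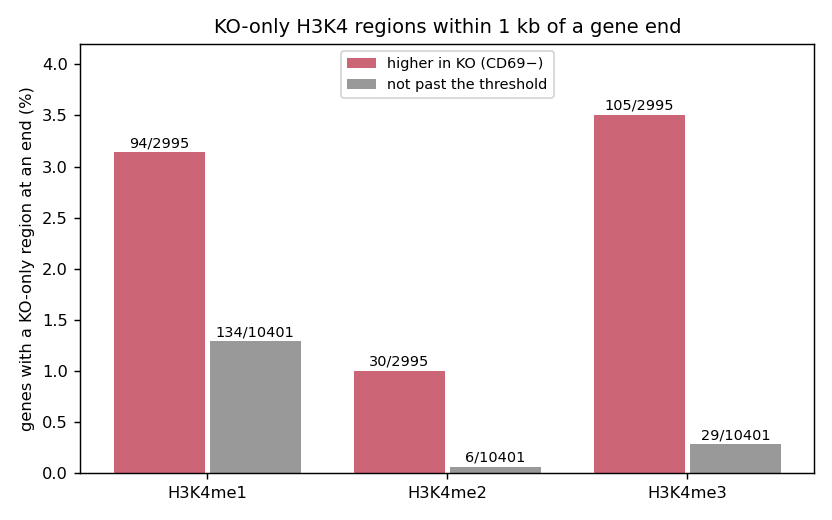
Percentage of genes with a KO-only region within 1 kb of a gene end (vertical axis), for genes higher in CD69-negative KO cells (2995) and genes without a call (10401), for each of the 3 H3K4 marks. For H3K4me3 it was 3.51% against 0.279%.

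In single cells, 4094 and 4789 WT and 2832 and 3215 KO cells were kept, with medians of 7210.5, 6878, 8675.5 and 5819 UMIs. The 2:1:1 mixture of sorted cells and the UMI threshold can set class shares, and 2 samples per genotype allow no exact permutation p below 0.333, so shares are given as values. B-like cells made up 2.43 ± 0.91% of cells in WT and 20.2 ± 11.6% in KO (SD, n = 2), 8.33 times as much, and 4.95 times without KO 2. DN2/DN3-like cells made up 16.2 ± 1.16% and 6.15 ± 1.35%, a ratio of 0.380, and with a minimum of 1000 UMIs 0.899% and 1.51% in WT and 0.934% and 0.492% in KO (ratio 0.593). Gamma delta-like cells made up 4.41 ± 0.12% and 1.65 ± 0.44%, and cycling cells 55.5 ± 2.95% and 48.3 ± 6.78%, a ratio of 0.871 that moved to 0.512 without centring. NK or innate-like cells made up 4.68 ± 0.50% and 6.05 ± 2.58%, a ratio of 1.29 that turned to 0.728 without centring, 0.730 with at most 5% mitochondrial UMIs and 0.904 without KO 1. DP-like cells made up 2.97 ± 0.47% and 8.74 ± 1.28%, a ratio of 2.95 that turned to 0.00608 without centring per sample and to 0.805 with a minimum of 1000 UMIs, so no direction is given. The gamma delta ratio of 0.375 turned to 1.25 without centring, and 13.9 ± 4.16% of WT and 8.90 ± 2.60% of KO cells stayed unnamed.

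DN2/DN3-like cells, which rearrange the TCR beta chain, came in WT and KO 1 mainly from one cluster and in KO 2 mainly from another. In KO, 356 genes were higher and 14 lower of 9737 tested (with the replicate block 645). Cd7, a surface receptor of lymphocytes, rose from 4.82 to 328 CPM (6.09 ± 0.21), the lectin gene Lgals3 by 7.52 ± 0.41, and the imprinted RNA H19 fell from 141 to 7.33 CPM (−4.30 ± 0.30). Cd163l1 rose by 3.10 ± 0.24. Interferon-stimulated genes were higher in 35 of 38 cases (camera adjusted p = 2.57e-58, 37 adjusted over the list alone). For this list and the 6 that follow here, adjusted p = 0.363 with an estimated correlation. With 2 samples per genotype that test can hardly pass any list, so it decides nothing in the single-cell classes. Ifi27l2a rose from 22.2 to 702 CPM (4.98 ± 0.26), Isg15 by 2.27 and Oasl2 by 3.28. Mature T cell genes were higher in 14 of 18 (adjusted p = 8.84e-22, 16 and 1 adjusted over the list alone), Klf2 by 3.99, Ccr7 by 3.83, Itgb7 by 5.05 and Ly6c1 by 3.68. Of 15 Bcl11b targets 5 were higher, Cd163l1, Runx3 (1.01), the integrin gene Itgae (2.32), Gzma (1.20) and Fcer1g (1.77; not called without KO 1, 1.36) (adjusted p = 1.29e-07, 8 and 1 adjusted over the list alone). Of 6 NK genes 3 were higher, Gzma, Fcer1g and Ctsw (1.06) (adjusted p = 9.59e-07, 5 adjusted over the list alone), and of 15 Bcl6 targets 5, among them Runx3, Klf2, Ccr7 and the receptor gene Gpr183 (3.39) (adjusted p = 3.89e-04, 6 and 2 adjusted over the list alone). B cell markers were higher in 7 of 9 cases (adjusted p = 1.91e-10, 8 adjusted over the list alone), the class II gene H2-Aa from 5.18 to 84.9 CPM, and the cell cycle list was lower with 0 members called (adjusted p = 6.08e-04, 0 adjusted over the list alone), a call lost without KO 2 (0.0679). Gfi1 stood at 0.58 (adjusted p = 0.221). Without KO 2, 668 genes were called.

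DP-like cells came mainly from a cluster of low depth in WT (median 3058 UMIs), led also by the mitotic genes Cenpf, Ube2c and Cdc20, and from another in KO (median 5252 UMIs). There, 414 genes were higher and 146 lower of 8219. The surface protein gene Ly6c1 rose from 12.3 to 990.4 CPM (6.31 ± 0.37), Itgb7 by 5.44, the class I gene H2-K1 by 3.80 and Klf2 by 4.19. Cd163l1, Il18r1 and Atp8b4, at 0 UMIs in WT, were at least 39.9-fold, 22.9-fold and 40.4-fold higher against a floor of 3 counts over the WT samples. Slc7a11 fell by −6.27 ± 0.56. Interferon genes were higher in 27 of 35 cases (adjusted p = 6.02e-26, 32 adjusted over the list alone) and mature T cell genes in 16 of 19 (adjusted p = 1.94e-23, 18 and 1 adjusted over the list alone). For both, adjusted p = 0.149 with an estimated correlation. The gamma delta (7 of 9 higher), Bcl11b (4 of 8, 1 lower), NK (3 of 3), Bcl6 (5 of 13), Gfi1 (4 of 12), stem (2 of 3), Notch (4 of 12) and TCR lists (4 of 17, 1 lower) rose (adjusted p = 2.37e-08, 1.18e-06, 9.95e-06, 1.38e-05, 0.00501, 0.00823, 0.0106 and 0.0426). For these, adjusted p = 0.149 to 0.286 with an estimated correlation. With at least 1000 UMIs the TCR list missed the threshold (adjusted p = 0.778, median −0.0766), and the B cell (0.0149) and epithelial lists (2.85e-04) passed. Calls were lost for the stem list without WT 1 (0.0535), KO 1 (0.243) or KO 2 (0.464), the Notch list without WT 1 (0.0526) or KO 2 (0.235), the TCR list without WT 2 (0.170) and the gamma delta list without KO 2 (0.0651). The B cell list (0.0973) passed with the replicate block (0.0222) and without WT 1 (0.0104) or WT 2 (0.00522). DP-stage genes fell in 2 of 22 cases, Ets2 (−2.02) and Dntt (−1.02) (adjusted p = 7.38e-06, 4 adjusted over the list alone, adjusted p = 0.459 with an estimated correlation). The call of Dntt was lost without WT 1 (−1.09) or WT 2 (−0.97). Cell cycle genes fell in 12 of 27 cases (adjusted p = 3.53e-10, 1 and 13 adjusted over the list alone, adjusted p = 0.330 with an estimated correlation), Cenpf by −3.03 ± 0.28 and Plk1 by −2.79. Both calls were lost with at least 1000 UMIs (−0.13 and −0.61). Without KO 2, 1148 genes were called, and with at least 1000 UMIs 2287.

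In the cycling class 1733 genes were higher and 584 lower of 12106 (4953 with the replicate block). Its cells lay partly in different clusters by sample: 1 cluster held 856, 1057, 81 and 3 cells of WT 1, WT 2, KO 1 and KO 2, another 9, 27, 833 and 86, and a further cluster 0, 0, 2 and 1035. Itgb7 rose from 1.34 to 132 CPM (6.63 ± 0.17), Ctss by 6.52, Cd163l1 by 6.27 and Gfi1 by 1.55 ± 0.17, and the protease gene Ctsl fell from 483 to 155 CPM (−1.64 ± 0.12). Interferon genes were higher in 35 of 38 cases (adjusted p = 4.57e-25, 37 adjusted over the list alone). For this and the lists that follow here, adjusted p = 0.380 to 0.459 with an estimated correlation. Mature T cell genes were higher in 19 of 21 (adjusted p = 8.16e-16, 20 adjusted over the list alone), Klf2 by 5.52 ± 0.32 and Ccr7 by 4.69, as were stem genes in 11 of 13 (adjusted p = 1.61e-05, 12 and 1 adjusted over the list alone). The Bcl6 (11 of 19 higher, 1 lower), Bcl11b (12 of 20), B cell (10 of 12, 1 lower), gamma delta (7 of 10, 1 lower), NK (7 of 15), epithelial (3 of 3), Notch (5 of 14), Gfi1 (7 of 18, 2 lower), germline (2 of 2), TCR (8 of 21, 1 lower) and dendritic lists (2 of 3) were higher (adjusted p = 1.81e-06 to 0.0259). Lower were the cell cycle (10 of 28 lower), H3K4 enzyme (1 of 16) and erythroid lists (3 of 4) (adjusted p = 2.92e-04, 0.0189 and 0.0189), Hbb-bs at −4.90 among the last. With at least 1000 UMIs Hbb-bs stood at −0.09, and the erythroid (adjusted p = 0.378) and dendritic lists (0.0859) missed the threshold. Without WT 2 or KO 1 the TCR (0.0969 and 0.112) and H3K4 enzyme calls (0.101 and 0.159) were lost, and without KO 1 also those of the Notch (0.0516), germline (0.0516) and dendritic lists (0.206).

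NK or innate-like cells had 155 genes higher and 26 lower of 7443 (520 with the replicate block; 46 in all without WT 1 and 92 without KO 1). The adaptor gene Tyrobp rose from 77.0 to 1015 CPM (3.71 ± 0.26), the NK receptor gene Ncr1 by 4.36, the chemokine gene Ccl5 by 2.01 and Cd163l1 by 4.96 ± 0.55, and the inhibitory receptor gene Klra9 fell by −2.80 ± 0.36. Tyrobp and Ncr1 were leading genes of a cluster of the class with 3 and 5 WT and 38 and 30 KO cells. NK genes were higher in 9 of 21 cases (adjusted p = 3.73e-09, 11 and 2 adjusted over the list alone). For this and the lists that follow here, adjusted p = 0.304 to 0.311 with an estimated correlation. Interferon genes were higher in 3 of 36, Usp18 (2.65), Oas1a (1.32) and Ifit1bl1 (1.56) (adjusted p = 2.47e-13, 7 adjusted over the list alone) and mature T cell genes in 6 of 20 (adjusted p = 6.23e-09, 11 and 1 adjusted over the list alone). The cell cycle list was lower with 0 members called (adjusted p = 4.39e-09, 9 lower adjusted over the list alone). The call of Oas1a was lost without WT 1 (1.15) or KO 1 (1.26), as was that of Ifit1bl1 (1.08 and 1.47). The B cell (5 of 7 higher), Bcl11b (6 of 20), dendritic (2 of 3), macrophage (2 of 2), stem (1 of 4), Gfi1 (3 of 12) and epithelial lists (1 of 2) were also higher (adjusted p = 1.52e-05 to 0.0247), and the Notch list lower with 0 of 9 called (adjusted p = 0.0228). With at least 1000 UMIs the Gfi1, Notch and stem lists missed the threshold (adjusted p = 0.247, 0.247 and 0.0501), and the Bcl6 (0.00395) and gamma delta lists (0.0260) passed. The Gfi1 call was also lost with the replicate block (0.0877) and without WT 2 (0.117) or KO 1 (0.193). The Notch call was lost without WT 1 (0.0613), WT 2 (0.323) or KO 1 (0.153), and the macrophage (0.0781) and epithelial calls (0.103) without WT 1. B-like cells came mainly from 1 cluster in WT (58, 119, 1 and 1 cells of WT 1, WT 2, KO 1 and KO 2) and from another in KO (8, 17, 259 and 856). In B-like cells edgeR called 1 gene of 8486, the variable segment Ighv14-4 (0.778 to 431 CPM), chosen after its value was seen. An unadjusted p under 0.05 was met by 503 genes, DESeq2 called 23 and the replicate block 27. The interferon, mature T cell and dendritic lists were higher there with 0 members called (adjusted p = 2.99e-05, 7.52e-05 and 0.0414, with 0, 4 and 1 adjusted over the list alone). For these, adjusted p = 0.833, 0.752 and 0.833 with an estimated correlation. The dendritic call was lost with the replicate block (0.0665) and without any single sample (0.0718 to 0.185).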

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

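Of the tests in this part, the pair on the rise of TCR signal genes was chosen only after the result was seen.

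The CD69 step differed by genotype in 1615 genes (edgeR interaction), mixing response and starting level. The log2 difference of the step, KO minus WT, was 3.20 for AI506816, 2.56 for Lap3, 2.52 for the polyamine gene Srm and 2.51 for Bcat1, and −3.65 for Tox2, −3.45 for the inhibitory receptor gene Btla, −3.44 for the chromatin remodeller gene Chd7 and −3.06 for Zbtb10, whose call was lost without CD69-negative WT 2 (−2.98), WT 3 (−3.07) or WT 4 (−2.93). Of the lists, mature T cell genes (adjusted p = 0.00140), Bcl6 targets (0.0200) and TCR signal genes (0.0200) had smaller steps in KO, while for cell cycle genes (0.0320) the test was positive. With an estimated correlation none held (adjusted p = 0.645, 0.753, 0.927 and 0.927). The dissociation stress list was also lower in the interaction with 0 members called (adjusted p = 0.0320; adjusted p = 0.927 with an estimated correlation). That call was lost without CD69-negative WT 4 (adjusted p = 0.0797), KO 1 (0.0823) or KO 2 (0.263) or CD69-positive WT 2 (0.0574), WT 3 (0.134), KO 3 (0.0610) or KO 4 (0.155), without the pair of libraries that stood apart (0.641) and with mitochondrial genes left out (0.0723). The TCR call was lost without CD69-negative KO 1 (0.0823) or KO 2 (0.0670) or CD69-positive WT 1 (0.0628) or KO 3 (0.0706), and the cell cycle call without CD69-negative WT 2 (0.0591) or KO 1 (0.0823) or CD69-positive WT 1 (0.198), WT 2 (0.248) or WT 4 (0.0913) and with sex as a term (0.0764). Without the pair of libraries that stood apart the TCR call (0.0518) and the Bcl6 call (0.0755) were lost.

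Among the named genes with the largest changes, single libraries stood far from the other libraries of their group. CD69-negative KO 2 held 481.3 CPM of Chd7, where the others held 452 to 454, and 269.3 CPM of Maf, with the others at 329. Smoc1 reached 91.5 CPM in CD69-negative WT 3 (others 59.9 to 65.2), Slc7a11 199.9 CPM in CD69-negative WT 4 (148 to 155), Inpp4b 11.5 CPM in CD69-positive KO 4 (6.19 to 6.81) and Gfi1 244 CPM in CD69-positive KO 2 (281 to 288). The histone gene Hist1h2af lay at 5.83 CPM in CD69-positive WT 3 (1.28 to 1.61), and Hist1h3c at 13.8 CPM in that library (2.80 to 3.49), at 92.1 CPM in CD69-negative WT 2 (68.9 to 70.2) and at 0.773 CPM in CD69-positive KO 2 (1.87 to 1.93). Lap3 lay at 1.57 CPM in CD69-negative KO 3 (3.65 to 3.91), Srm at 9.01 CPM in CD69-negative WT 2 (4.94 to 5.55) and Btla at 13.0 CPM in CD69-negative KO 3 (15.5 to 15.7). These are 13 of 154 groups of 4 libraries, where chance alone gives about 5%, or 7.7.

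TCR signal genes, Cd69 among them, were higher in KO cells of the CD69-negative gate. If average CD69-positive cells in the gate were the whole cause, the 15 called genes would need a median share of 23.08% (0.877% to 50.8%). Of 64 other genes rising strongly in the WT step, the lowest allows 0.642% and the fifth lowest 4.82%. All of the 15 but Tnfrsf9 and Bcl2a1d need more than 4.82%. This argues against such cells as the whole cause of their rise. Dissociation stress cannot be told apart from the signal. Outside the stress list 13 of 24 members (54.17%) were higher. That count follows from the 15 of 26 of the whole list and includes Egr2, Egr3, Nr4a2 and Nr4a3, which stress may also raise. Cells just signalled but not yet positive for CD69, or a direct effect of Lsd1 loss, also stay open as hypotheses.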

How the results depend on the processing

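Of the tests here, sex as a term, leaving out mitochondrial genes, leaving out the pair of libraries that stood apart, a minimum of 1000 UMIs or a limit of 5% mitochondrial UMIs for class shares, and leaving out samples for gene ends, class shares and single-cell lists were chosen only after the results were seen. Over 8225 alternatives for 460 bulk gene values, 7987 kept direction and call, 116 lost the call, 122 gained one and 0 changed sign; over 3731 for 300 single-cell values it was 3490, 136, 99 and 6. The cause of the changes below was not tested unless stated. Of 456 alternatives to the 48 counts and ratios that answer a comparison, 369 stayed within 1.5 times or the spread. Where leaving out a sample left a lone one, it was assumed to vary like the other groups.

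Bulk gene counts without any single library ran from 5460 to 6203 (CD69-negative), 5799 to 6732 (CD69-positive), 6391 to 7812 (WT step), 6630 to 8113 (KO step) and 1082 to 1756 (interaction). Sex as a term gave 6499, 7153, 8079, 8135 and 1791. With the replicate number as a block the KO step had 5 lists. In the interaction, not taken as paired, it gave 2516 genes (1379 positive, 1137 negative) and passed the interferon list (adjusted p = 0.0131). Each library correlated best with its own number in the directly compared groups but not in the others. Beyond what is given here, beside the comparisons and among the other observations, the block changed no call of a list or of a gene whose value is printed. With an estimated correlation 4 lists held in the CD69-negative gate, 6 in the CD69-positive gate, 0 in the steps and the interaction, and 0 in each single-cell class. That test allows for correlated genes. With 2 samples per genotype it can hardly pass any list, so it decides nothing in the single-cell classes. In DN2/DN3 all 7 lists stood at 0.363, though camera at the preset correlation gave adjusted p from 2.57e-58 to 6.08e-04. With fry, which compares no list with other genes, 10 lists passed in the WT step, 12 in the KO step and 1 in the interaction. Without the pair of libraries that stood apart the KO step had 5 lists, and without single libraries 3 to 5, the interaction 2 to 6.

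In single cells the replicate number served as a block. Same-number correlations were 0.133 in B cells, 0.299 in DN2/DN3, −0.0304 in DP, 0.251 in NK and 0.487 in cycling cells. It gave 27, 645, 520 and 4953 genes in B, DN2/DN3, NK and cycling cells, and changed the list calls given beside them. Without single samples, lists that had no call gained one in every class but the cycling one. DESeq2 called 23 genes in B, 359 in DP and 100 in NK cells. Without a filter it was 237 in B, 661 in DN2/DN3 and 391 in NK cells, with more low genes tested. With at least 1000 UMIs it was 6 in B, 2287 in DP and 357 in NK cells; NK cells gave 721 without centring and 688 with at most 5% mitochondrial UMIs. Under these 2 settings Ikzf2 (−0.23 and −0.21) and Tnfrsf9 (−0.12 and −0.15) changed sign in NK cells, as did Hba-a2 (0.86) and Hba-a1 (0.62) in cycling cells with at least 1000 UMIs. Leaving out a sample gave 9 (without WT 2) to 64 genes (KO 2) in B, 354 to 668 (KO 2) in DN2/DN3, 391 to 1148 (KO 2) in DP, 46 (WT 1) to 263 in NK and 1420 (WT 1) to 2668 in cycling cells.

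Ratios of class shares, KO over WT, with at least 1000 UMIs were 0.593 for DN2/DN3, 0.805 for DP, 0.278 for gamma delta and 0.315 for unnamed cells. Without centring they were 0.00608 for DP, 0.728 for NK, 0.512 for cycling, 1.25 for gamma delta and 3.39 for unnamed cells, and with at most 5% mitochondrial UMIs 0.730 for NK and 1.13 for gamma delta. Leaving out a sample gave 4.95 (KO 2) to 11.7 for B, 0.322 to 0.439 for DN2/DN3, 0.904 to 1.68 for NK and 0.305 to 0.445 for gamma delta cells.

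With peaks above the median score, the H3K4me2 length ratio was 0.940, and regions numbered 2477 (H3K4me1, KO-only), 1438 (H3K4me2, WT-only), 285 (H3K4me3, KO-only) and 29 (H3K4me3, WT-only). Leaving out a library gave length ratios of 0.835 to 1.73 for H3K4me1 and 0.961 to 1.13 for H3K4me2; 5226 to 13395 (WT 1) KO-only and 866 (KO 2) to 9504 (WT 1) WT-only regions for H3K4me1, 436 to 1616 (KO 1) and 2658 to 6664 (KO 2) for H3K4me2, and 441 to 1215 (KO 1) and 8 to 48 (WT 3) for H3K4me3, since fewer libraries must match. Odds ratios at gene ends were 1.15 to 2.70, 6.34 to 14.8 and 4.00 to 13.7. Peak numbers were not tested in pairs. KO lay above the same-numbered WT library in both pairs of H3K4me1, below it in both of H3K4me2 and on either side for H3K4me3.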

Other observations

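Of the tests in this part, those on other splits of the bulk libraries and the comparison of free RNA with B-like cells were chosen only after the results were seen; the others on free RNA, B cells and library quality were set before their results.

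Genes of gamma delta T cells rose in DP cells of KO mice, which are alpha beta lineage cells by their gate. Of 10 tested, 8 were higher and 0 lower in CD69-negative cells (camera adjusted p = 6.69e-07; 8 adjusted over the list alone; adjusted p = 0.0531 with an estimated correlation) and 7 in CD69-positive cells (adjusted p = 2.46e-05; 7 adjusted over the list alone; adjusted p = 0.0985 with an estimated correlation). The gamma constant gene Tcrg-C2 rose from 0.324 ± 0.0204 to 14.9 ± 3.41 CPM before the TCR signal (5.49 ± 0.27, n = 4) and by 6.39 after it, where Tcrg-C1 rose by 5.59. The delta constant gene Trdc, chosen after its values were seen, stood at 45.4 ± 7.06 CPM in WT and 45.2 ± 3.62 CPM in KO. The list's other leaders, Cd163l1, Blk and Maf, are also among the genes with the largest rises.

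Genes of dissociation stress, several of them immediate early genes that TCR signals induce, were higher in 10 of 15 cases in CD69-negative KO cells (adjusted p = 9.21e-04; 11 adjusted over the list alone; adjusted p = 0.383 with an estimated correlation). Fos rose from 30.5 to 363 CPM (3.57 ± 0.59), Fosb by 3.80, Nr4a1 by 3.22 and Egr1 by 1.35, and Hsp90aa1 stood at 0.24. In CD69-positive cells 3 were higher, Atf3 (5.29), Fosb (2.31) and Fos (1.91), and the list missed the threshold (adjusted p = 0.0919), passing with the replicate number as a block (0.0225) and without CD69-positive WT 3 (0.0392), KO 4 (0.0373) or the pair of libraries that stood apart (0.0128). The WT step raised 9 (adjusted p = 0.00146; 10 adjusted over the list alone; adjusted p = 0.763 with an estimated correlation), among them Junb (2.69).

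The B cell list was higher in KO in the DN2/DN3 (adjusted p = 1.91e-10), NK (1.52e-05) and cycling classes (1.68e-05) of the single-cell samples, and missed the threshold in the DP class (0.0973). None held with an estimated correlation (adjusted p = 0.363, 0.304 and 0.380), a test that can hardly pass any list with 2 samples per genotype. In DN2/DN3-like cells class II transcripts made up 365 and 482 CPM in KO and 7.14 and 80.5 in WT. Free RNA in droplets with few UMIs held 2260.0 and 3693 CPM in KO and 738 and 842 in WT. If free RNA were the source, the ratio of class II to B lineage UMIs would be alike in cells and free RNA, and the KO library farther from 1 gave 1.409 in DN2/DN3, 1.423 in DP, 1.783 in NK and 1.738 in cycling cells, within the bounds of 0.5 and 2 set beforehand. The B-like cells of KO also lay within them (0.692 and 0.889), so free RNA cannot be told apart from B cells caught with another cell. The counting intervals of both KO samples lay above 1 in DN2/DN3 (1.01 to 1.78 and 1.05 to 1.92), NK (1.16 to 2.19 and 1.11 to 3.02) and cycling cells (1.46 to 2.08 and 1.15 to 1.65). In WT the ratio was 3.21 (1.99 to 5.33) and 2.03 (1.44 to 2.88) in cycling cells and, from few UMIs, 2.43 (0.355 to 104) in NK cells of WT 1. Free RNA, doublets and expression in the cells themselves all stay open.

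KO-only regions of H3K4 methylation lay at the ends of genes higher in KO. Since B cells were more frequent among KO cells in the single-cell samples, more B cells in whole thymus were weighed, but among 6932 genes low in B cells the odds ratio was 2.485 (1.70 to 3.63) for H3K4me1, 27.64 (6.74 to 243) for H3K4me2 and 7.639 (4.50 to 13.5) for H3K4me3, and of 10 B cell markers 0 had such a region, which argues against B cells as the whole cause. Library quality that differs whatever the genotype would give other splits of the libraries ratios as high. The highest with at least 100 regions was 1.669, 1.507 and 1.605, below the lower bounds by genotype of 1.88, 7.17 and 8.52. Of the other splits, 4 of 4, 2 of 4 and 2 of 18 had that many regions. Some smaller H3K4me3 splits gave higher ratios from few genes, such as 5.21 (0.597 to 62.4). Every other split mixes the genotypes, so a difference in quality that goes with genotype stays open. For H3K4me1 the gap to the other splits rests on WT 2, without which the ratio by genotype was 1.15. It fell to 6.34 for H3K4me2 (without KO 1) and 4.00 for H3K4me3 (without WT 3). Whether Lsd1 acts at these ends may be asked as a hypothesis, and other changes in cell mixture stay open.

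Other splits of the bulk libraries tested whether chance could give as many called genes. In the CD69-negative gate 1 of 35 splits, the real one, gave as many (6458, highest other 0), and in the CD69-positive gate 1 of 35 (6929, highest other 37). It was 1 of 35 in the WT step (7812, highest other 0) and in the KO step (7828, highest other 422, from exchanging CD69-negative KO 2 with CD69-positive KO 4). In the interaction it was 1 of 60 drawn (1615, highest other 676). In the direct comparisons every other split mixes the groups compared, so a real difference widens its spread and lowers its count. Over splits that ignore the replicate number chance can be excluded for the first 4 counts, though not for each called gene. The draws for the interaction also remove the difference between genotypes within each gate. They therefore do not decide whether chance could give its 1615 genes. The 8 splits that part every pair, the real one included, are too few for a share under 0.05, and the highest other of them gave 0 in each of the first 4. No draw for the interaction kept the pairs. For the number of lists chance cannot be excluded by this count: 11, 5, 7 and 28 of 35 splits and 44 of 60 gave as many as the real 14, 14, 6, 3 and 5, with highest others of 17, 15, 8, 9 and 18. In the 2 gates and the WT step every other split that did so exchanges 1 library each way and keeps part of the real difference, and those that exchange 2 each way gave at most 6, 6 and 5 lists, so the count says little there. In the KO step the latter reached 9, and camera at a preset correlation does not estimate how far a list's genes vary together.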
